A study of Caenorhabditis elegans with 6 samples.

How the data were processed

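The series holds 6 RNA-seq libraries of total RNA from *C. elegans*, 3 labelled control and 3 labelled JM03, and each library was placed in its group by its treatment label. Stage, dose and length of exposure are not given in the sources used here. The authors deposited 1 table with a TPM value, at 2 decimals, for each gene in each library. That its unit is TPM was taken from the values, since the columns sum to 997816 to 998884, just under the fixed total of that unit. Per the submitters' processing notes the tools were fastp, HISAT and RSEM and the build was WBcel235. Versions, settings, the annotation release and whether the counting used strand are not given in the sources used here. Without strand, overlapping genes on opposite strands cannot be told apart, and reads of near-identical genes may be split between copies.

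Gene symbols were those of the table, except in 11 rows where a spreadsheet had turned the symbol into a date and 210 rows with none, where the symbol was looked up by gene ID. Of 46778 rows, 43818 matched the reference name table and 46603 the WBcel235 annotation, which gave coordinates, gene type and transcript length. No columns of libraries were identical. None of the 81 ribosomal protein genes was at 0 in any library, but an exact 0 can also be a failed estimate. Genes at 0 throughout a group are therefore described as listed at 0, with TPM values and no fold.

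The values are not read counts, so the test planned for counts was not used and the branch planned for normalized values was. Values were analysed as log2(TPM + 1) for the 12912 genes with at least 1 TPM in at least 3 libraries. JM03 was compared with control by limma 3.58.1 in R 4.3.3, with a mean-dependent and robust prior (limma-trend), without pairing. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. For 44 gene lists of pathways, families and cell type markers, camera was run with a preset correlation of 0.01, again with an estimated correlation, and fry beside it, each adjusted over the lists. Classes of at least 10 tested genes whose symbols share the letters before the hyphen were tested with Fisher's exact test and with camera. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

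The comparison, its test, the lists, the rule for named genes and the first group of alternative settings were fixed before the data were examined. The text names 12 fixed candidates, the called genes of largest log2 fold change in each direction with a mean of at least 5 TPM and all JM03 values on one side of the controls, up to 4 called members of a list or its member of smallest p, and up to 3 called members of a symbol class. Names outside this rule are said to be so where they appear. Those settings were quantile normalization, no filter, a filter at 5 TPM, a 2-fold minimum, a pseudocount of 0.1, a non-robust prior, the replicate number as a block, and each library left out. Settings foreseen for read counts were not run. Array quality weights with 2 estimators, rescaled protein-coding genes, and quantile normalization without control replicate 3 were added after seeing the data.

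The limma step was tested on simulated values for the 12912 genes with 200 changed genes, drawn from those with a mean of at least 3 in log2(TPM + 1). Most of the genes called in the real data lie below that mean, so the shares do not describe them. The simulated noise was independent between libraries and genes, while in the data much of the spread lies in control replicate 3. With the spread of the 6 libraries the limma step recovered 0% of 67 genes changed by 1 on the log2 scale, 37.3% of 67 changed by 2 and 68.2% of 66 changed by 4, with 3 false among 73 calls. With the spread of the 5 libraries without control replicate 3 the shares were 67.2%, 85.1% and 98.5%, with 7 false among 174 calls.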

Results

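RNA from the nematode *Caenorhabditis elegans* was sequenced in 6 libraries, 3 from animals given JM03, which the series title calls a derivative of crotamiton, and 3 from control animals. The deposited table gives TPM, a length-scaled share of transcripts, for 46778 genes, of which 26164 were listed at 0 in all 6 libraries and 12912 were tested. TPM keeps no read depth, so the depth behind each value is unknown. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

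Control replicate 3 stood apart from the other 5 libraries. Its Spearman correlations with them across genes were 0.784 to 0.866, against 0.901 to 0.978 among the others. It had 16560 genes above 0, where the others had 18049 to 18208, and 4.37% of its TPM lay on ribosomal RNA, against 0.34% to 0.64%. Cytosolic ribosomal protein genes took 38.69% of its TPM, against 25.5% to 30.65%. Long transcripts were low in it: across genes, its deviation from each gene's median over the 6 libraries had a Spearman correlation of -0.55 with transcript length, against -0.004 to 0.152 in the others, where genes are not independent replicates. The median log2 fold change over all tested genes was 0.35 with the 6 libraries and 0.046 without control replicate 3, and 72.7% and 56.5% of the tested genes had a positive one. List changes are therefore given relative to the median of all genes. This removes a shift common to all genes but not one that follows transcript length.

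**Figure D1:**
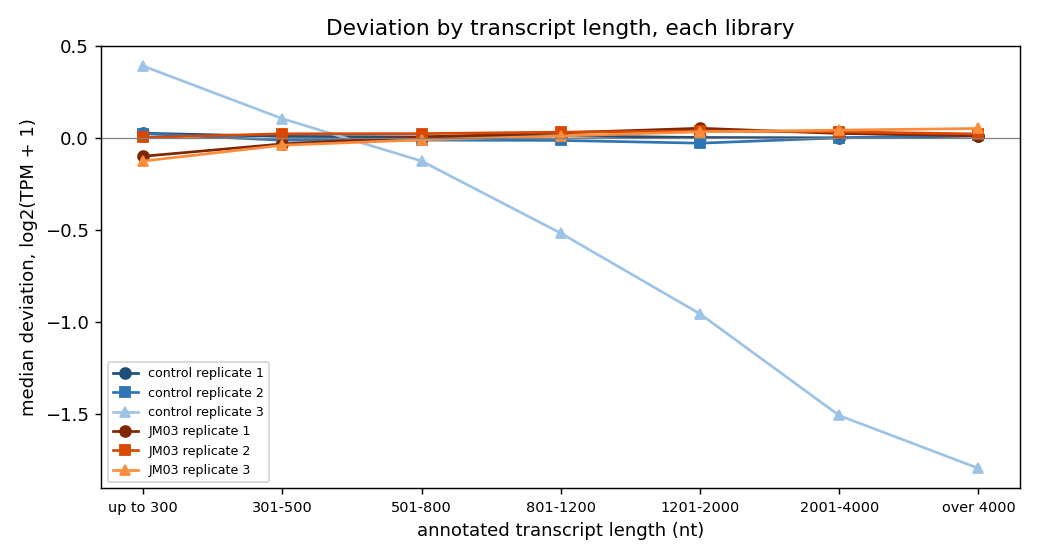
Median deviation of protein-coding genes from their median over the 6 libraries in log2(TPM + 1), on the y axis, by annotated transcript length in nucleotides, on the x axis, with one line per library. Control replicate 3 goes from 0.39 for transcripts of up to 300 nt to -1.79 for those over 4000 nt, while the other 5 libraries lie between -0.125 and 0.053 throughout.

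The comparison of JM03 with control asked which genes differed in the treated animals. Of the 12 genes higher in JM03, 5 were cytochrome P450s, monooxygenases that oxidise foreign compounds and lipids. The P450 gene *cyp-14A3* (WBGene00010707, X:13271837 to 13274202 in WBcel235) had 72.6 ± 13.2 TPM in JM03 and 0.907 ± 0.577 in control (mean ± SD, n = 3 each), with a log2 fold change of 5.30 ± 0.341 (SE; limma, Benjamini-Hochberg adjusted p = 0.00314). Its neighbour *cyp-14A2* (WBGene00010706, X:13267562 to 13269686) had 12.64 ± 2.01 against 0.18 ± 0.18 TPM (log2 fold change 3.53 ± 0.262, limma adjusted p = 0.00576). On chromosome V, *cyp-34A10* (WBGene00015045) had 18.6 ± 4.76 against 0.227 ± 0.162 TPM, and *cyp-35A3* (WBGene00019565) had 13.9 ± 3.24 against 0.36 ± 0.0529 TPM (log2 fold changes 3.98 and 3.43, limma adjusted p = 0.00576 and 0.00625). The fifth P450, *cyp-35A5*, had 5.22 ± 1.59 against 0.147 ± 0.0643 TPM (log2 fold change 2.41, limma adjusted p = 0.0342). Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes.

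The largest log2 fold change was that of R09E12.9 (WBGene00044514, V:777600 to 778245), at 301.1 ± 51.1 TPM in JM03 and 2.89 ± 1.70 in control (6.35 ± 0.394 SE, limma adjusted p = 0.00314). H25K10.4 (WBGene00010413, IV:16226047 to 16227122) was listed at 0, 0.93 and 0.59 TPM in the controls and at 97.96, 99.17 and 69.0 TPM in JM03 (5.93 ± 0.359, limma adjusted p = 0.00314). The short-chain dehydrogenase gene *dhs-23* (WBGene00000986) had 14.7 ± 2.84 against 0.29 ± 0.372 TPM (3.62 ± 0.311, limma adjusted p = 0.0114). T10B5.8 and R05D8.9 had log2 fold changes of 2.74 and 1.94 (limma adjusted p = 0.015 and 0.0337). F38C2.1 was listed at 0 in every control and at 8.29, 9.24 and 8.70 TPM in JM03, and C37A5.5 at 0 in every control and at 1.87, 2.56 and 2.53 TPM in JM03 (limma adjusted p = 0.00314 and 0.0337).

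All 5 genes lower in JM03 were listed at 0 in its 3 libraries and had transcripts of 122 to 226 nt. The non-coding RNA E03H12.27 (WBGene00235378) had 18.76, 18.55 and 25.56 TPM in the controls, and the non-coding RNA Y41E3.465 (WBGene00235107) 10.58, 20.80 and 16.79 TPM (limma adjusted p = 0.00314 and 0.00576). The small nuclear RNA genes F08G2.11 and F38E11.11 had 8.47 to 21.06 and 9.28 to 28.27 TPM in the controls (limma adjusted p = 0.015 and 0.0201). The protein-coding T11F9.22 had 4.52 to 12.56 TPM there (limma adjusted p = 0.0412). *cyp-35A5*, T10B5.8, R05D8.9, F38C2.1, C37A5.5 and T11F9.22 fell outside the rule for named genes and were chosen after their values were seen.

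**Figure D2:**
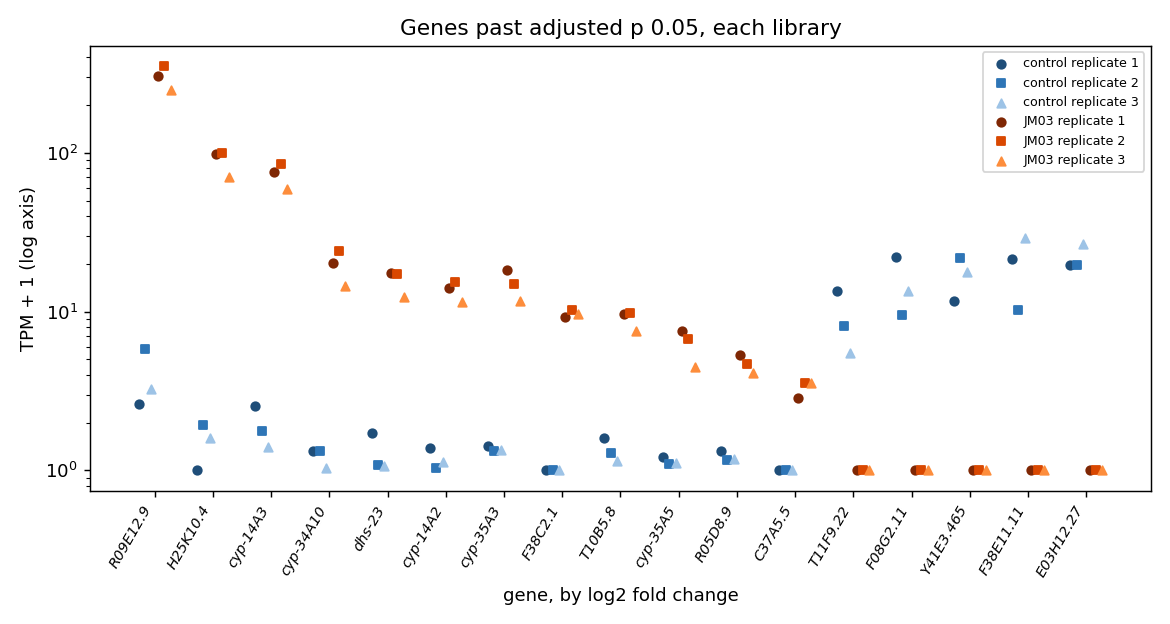
TPM + 1 on a log y axis of the 17 genes past adjusted p 0.05, ordered along the x axis by log2 fold change, with one point per library (blue, 3 controls; orange, 3 JM03). For each gene the 3 JM03 points lie on one side of the 3 controls, and the 5 genes at the right are listed at 0 in all JM03 libraries.

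In all, 17 of the 12912 genes passed a limma Benjamini-Hochberg adjusted p of 0.05, 12 higher and 5 lower, and 1517 had an unadjusted p below 0.05. Without control replicate 3 there were also 17, 10 higher and 7 lower, of which 13 were shared. *cyp-35A5*, R05D8.9, C37A5.5 and F08G2.11 were not called there (limma adjusted p = 0.108, 0.0834, 0.0839 and 0.0719). The log2 fold changes of *cyp-35A5* and R05D8.9 were 2.39 and 1.91 there, against 2.41 and 1.94 with the 6 libraries. C37A5.5 and F08G2.11 were at 0 and 12.56 TPM in control replicate 3, within the range of the other controls. *cyp-34A9*, at 70.9 ± 10.8 TPM in JM03 and 18.3 ± 5.95 in control, was called there (limma adjusted p = 0.0231) together with *msp-74* and the overlapping non-coding F16A11.7 and F16A11.9. F16A11.7 and F16A11.9 were each listed at 3.13 and 2.99 TPM in control replicates 1 and 2 and at 0 in all JM03 libraries. Both are annotated at the same coordinates (I:9382980 to 9383170), so the 7 lower genes count that locus more than once. *cyp-34A9*, F16A11.7 and F16A11.9 too were chosen after their values were seen. The count was 8 without control replicate 2, and 5, 6 and 10 without JM03 replicates 1, 2 and 3. The genes called under each omission of a single library were *cyp-14A3*, R09E12.9, H25K10.4, F38C2.1 and E03H12.27. A pseudocount of 0.1 gave 13 calls, 7 higher and 6 lower, and ended those of H25K10.4, T10B5.8, C37A5.5, *dhs-23* and R05D8.9 (limma adjusted p = 0.0571 for the first 3, 0.0697 and 0.0694). Quantile normalization ended those of F38E11.11, *cyp-35A5* and R05D8.9 (limma adjusted p = 0.113, 0.0761 and 0.104), and no filter on low values those of *cyp-35A5*, R05D8.9 and T11F9.22 (limma adjusted p = 0.0669, 0.0656 and 0.079). With the replicate number as a block 0 genes were called, so all 17 calls ended. Their log2 fold changes were unchanged and their limma adjusted p ran from 0.0679 to 0.269.

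Among the 44 gene lists fixed beforehand, the cytochrome P450s had 48 tested members, 47 with a positive log2 fold change (41 without control replicate 3). Of these 5 were called over all genes and 12 when adjusted over the list alone, and the median relative to all genes was 0.30 (limma camera with a preset correlation, adjusted p = 1.2e-10). The UDP-glucuronosyltransferases, which conjugate foreign compounds to sugars, had 46 tested members, all with a positive log2 fold change (41 without control replicate 3) and a relative median of 0.32 (camera adjusted p = 1.4e-07). None of them was called over all genes and 8 were when adjusted over the list alone, and with quantile normalization *ugt-63* was called over all genes (log2 fold change 2.01, limma adjusted p = 0.0239, against 0.0695). The glutathione S-transferases had 34 tested members, 30 positive, none called and 1 when adjusted over the list alone, with a relative median of 0.17 (camera adjusted p = 0.012). All 3 of these list calls were lost with an estimated correlation (adjusted p = 0.867 for each with an estimated correlation). Control replicate 3 was the lowest library for the P450 and UDP-glucuronosyltransferase medians, and without it the relative medians of the 3 lists were 0.35, 0.35 and 0.46. With a pseudocount of 0.1 that of the UDP-glucuronosyltransferases was 0.57. The glutathione S-transferase call also ended with quantile normalization (0.20, camera adjusted p = 0.066), and without control replicate 2 its median turned to -0.11 (camera adjusted p = 0.449). The 17 intestine markers had a relative median of 0.24 and were not called (camera adjusted p = 0.143), with median deviations from each gene's mean over the 5 libraries other than control replicate 3 of 0.22, -0.51 and -0.95 in the controls and 0.23, 0.02 and 0.095 in JM03. Without control replicate 1 they were called (0.36, camera adjusted p = 0.0128), and without control replicate 2 their median was -0.046 (camera adjusted p = 0.949). Without JM03 replicate 1 it was 0.11 (camera adjusted p = 0.305). Array quality weights and the gene-by-gene estimator called the intestine markers (0.36 and 0.30, camera adjusted p = 0.00273 and 0.0123).

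The sperm gene lists had lower medians in JM03. The 31 tested major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, all had a negative log2 fold change, with a relative median of -1.97 (camera adjusted p = 1.5e-34). None was called over all genes and 30 were lower when adjusted over the list alone. *msp-74*, listed at 2.66, 3.75 and 8.14 TPM in the controls and at 0 in all JM03 libraries, was called over all genes in some other fits. These were the fit without control replicate 3 and that with a pseudocount of 0.1 (limma adjusted p = 0.0428 and 0.0416). Array quality weights called it too (limma adjusted p = 7.98e-04, and 0.00189 with the gene-by-gene estimator). The 2 array weight fits, added after the data were seen, called 2202 and 97 of the 12912 genes. Of 27 sperm markers, 24 were negative, with a relative median of -1.35 (camera adjusted p = 3.8e-14). None was called over all genes in the main fit and 7 were lower when adjusted over the list alone. With array quality weights *ssp-9* was called (limma adjusted p = 0.0163, and 0.0451 with the gene-by-gene estimator). Both list calls were lost with an estimated correlation (adjusted p = 0.867 for each with an estimated correlation). Control replicate 3 had the highest major sperm protein median, and without it the relative medians were -1.417 and -1.099. Major sperm protein genes are near-identical copies, so reads can be split among them and their values are not independent.

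The 23 oocyte markers all had a positive log2 fold change, with a relative median of 0.71 (camera adjusted p = 3.2e-04), which was 0.32 without control replicate 3, the lowest library for this list. The collagens had 58 tested members, 47 positive, with a relative median of 0.49 (camera adjusted p = 0.012), which was 0.87 without control replicate 3 or with a filter at 5 TPM, and the 18 body wall muscle markers were all positive, with a relative median of 0.60 (camera adjusted p = 0.0051). The 81 cytosolic ribosomal protein genes had a relative median of -0.62 (camera adjusted p = 1.2e-16), which was -0.23 without control replicate 3, the highest library for this list, -0.175 with quantile normalization (camera adjusted p = 0.0158) and -0.40 with no filter on low values. No member of the oocyte, collagen, muscle and ribosomal protein lists was called over all genes in the main fit, and all 4 list calls were lost with an estimated correlation (adjusted p = 0.867 for each with an estimated correlation). With array quality weights *col-3*, *perm-2* and *rpl-39* were among the 2202 genes called (limma adjusted p = 0.016, 0.025 and 0.0243). Adjusted over the list alone, 1 collagen was higher and no other member passed. The collagen call also ended with no filter on low values, where the median turned to -0.016 (camera adjusted p = 0.556), and without control replicate 2 or JM03 replicate 3 (0.06 and 0.14, camera adjusted p = 0.763 and 0.0678), and that of the muscle markers ended without control replicate 2 (0.45, camera adjusted p = 0.0592) and without JM03 replicate 3 their median was 0.35.

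A further 8 lists were called higher, namely the epidermis markers (relative median 0.77), molting genes (0.50), longevity regulators (0.41), lipid breakdown and fasting response genes (0.28), intestinal immune response genes (0.26), autophagy and lysosome genes (0.24), drug efflux transporters (0.20) and nuclear hormone receptors (0.04), with camera adjusted p of 0.012 to 0.045 and no member called over all genes. All 8 calls were lost with an estimated correlation (adjusted p = 0.867 for each with an estimated correlation). The 10 epidermis markers, all positive, had the highest relative median of the 44 lists. Without control replicate 3, the lowest library for them, 7 were positive, their median was 0.48 and the call ended (camera adjusted p = 0.174), as did those of the molting genes, longevity regulators and lipid breakdown genes (0.38, 0.075 and 0.15, camera adjusted p = 0.182, 0.144 and 0.102). The epidermis call also ended at 5 TPM and without control replicate 2 or JM03 replicate 3 (camera adjusted p = 0.090, 0.0795 and 0.0771). A filter at 5 TPM also ended the calls of the immune, autophagy, drug efflux and longevity genes (camera adjusted p = 0.05002, 0.05002, 0.237 and 0.0942), and no filter on low values that of the nuclear hormone receptors (0.013, camera adjusted p = 0.0708). Without control replicate 2 the immune, lipid breakdown, molting and nuclear hormone receptor calls ended (camera adjusted p = 0.434, 0.0511, 0.0674 and 0.0648), and the immune median was -0.042. Without JM03 replicate 3 the molting median was 0.125 (camera adjusted p = 0.0678). The nuclear hormone receptor median was 0.27 at 5 TPM, and the drug efflux median 0.47 with a pseudocount of 0.1.

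**Figure D3:**
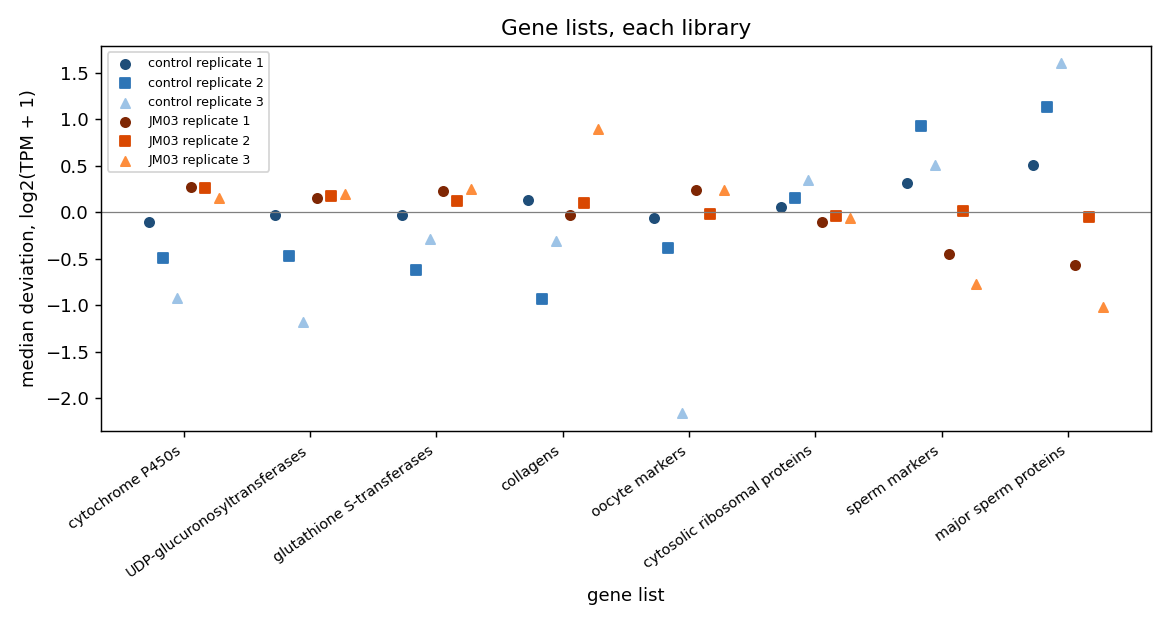
Median deviation in log2(TPM + 1) of the members of 8 gene lists, on the y axis, from each gene's mean over the 5 libraries other than control replicate 3, with one point per library (blue, 3 controls; orange, 3 JM03) and the lists on the x axis. The major sperm proteins lie between 0.51 and 1.60 in the controls and between -1.01 and -0.05 in JM03, and control replicate 3 is at -2.16 for the oocyte markers.

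The series title names the channel gene *osm-9* and resistance to oxidative and hypertonic stress. *osm-9* was listed at 0.28, 0.25 and 0.04 TPM in the controls and 0.29, 0.27 and 0.36 in JM03, and it and its partner *ocr-2* lay below the filter and were not tested. The SKN-1 target genes had 16 tested members, all with a positive log2 fold change and a relative median of 0.06 (camera adjusted p = 0.0468), and the 16 osmotic stress response genes, also all positive, had 0.34 (camera adjusted p = 0.0168). The 13 DAF-16 activated genes, all positive, had 0.22 (camera adjusted p = 0.0031), and the 9 DAF-16 repressed genes, 8 of them positive, had 0.12 and were not called (camera adjusted p = 0.487). The median of the repressed genes was 0.54, -0.055 and 0.018 without control replicates 1, 2 and 3, and 0.32 with quantile normalization. None of these fits called them (camera adjusted p = 0.0823 to 0.944). Of all tested genes, 72.7% were positive with the 6 libraries and 56.5% without control replicate 3. Without it, 14 SKN-1 targets, 15 osmotic genes, 13 DAF-16 activated genes and 5 DAF-16 repressed genes were positive. The relative medians of the 3 called lists were then 0.33, 0.16 and 0.45. The calls too were lost with an estimated correlation (adjusted p = 0.867 for each with an estimated correlation), and no member of the 3 lists was called over all genes in the main fit. Without control replicate 2 the medians of the SKN-1 targets and osmotic genes were -0.04 and 0.38 and neither list was called (camera adjusted p = 0.251 and 0.0601), and the SKN-1 call also ended without control replicate 1 and without JM03 replicate 1 or 3 (camera adjusted p = 0.1003, 0.0604 and 0.0771). A filter at 5 TPM ended both calls, with medians of 0.23 and 0.21 (camera adjusted p = 0.0664 and 0.0942), and quantile normalization and rescaled protein-coding genes ended the SKN-1 call (0.09 and 0.05, camera adjusted p = 0.124 and 0.0687). With no filter on low values the 3 medians were 0.28, 0.53 and 0.43, and that of the SKN-1 targets was 0.21 with a pseudocount of 0.1. The DAF-16 median was 0.42 with quantile normalization and 0.38 with either a filter at 5 TPM or that pseudocount. Adjusted over the list alone, 1 SKN-1 target, 1 DAF-16 activated gene and no osmotic gene were higher. The 22 antioxidant enzymes had a relative median of 0.02 (camera adjusted p = 0.29).

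None of the 10 fixed candidates that could be tested was called in the main fit. With the spread of the 6 libraries, 0% of 67 simulated genes changed by 1 on the log2 scale were recovered. The lack of a call therefore says little about changes of that size. The metallothionein gene *mtl-1* had 427 ± 27.2 TPM in JM03 and 132 ± 38.9 in control (log2 fold change 1.73, limma adjusted p = 0.16). The log2 fold changes were 1.01 for *gst-4*, 0.95 for *gpdh-1*, 0.91 for *hmit-1.1*, 0.57 for *sod-3*, 0.23 for *nlp-29* and -0.22 for *hsp-16.2* (limma adjusted p = 0.306 to 0.659). *skn-1*, *gcs-1* and *daf-16* had 0.92, 0.61 and 0.54 (limma adjusted p = 0.49 to 0.549), and control replicate 3 was low for all 3 of them. Without it, *skn-1* was at 0.13, *gst-4* at 0.76 and *hmit-1.1* at 1.08, and *gcs-1* and *daf-16* turned to -0.12 and -0.07. For *mtl-1*, *gpdh-1*, *hmit-1.1* and *skn-1* every JM03 value lay above every control value, while for the other tested candidates the groups overlapped. With array quality weights, *mtl-1*, *gst-4*, *gpdh-1* and *hmit-1.1* were called (limma adjusted p = 0.00384, 0.0456, 0.0262 and 0.0243). With the gene-by-gene estimator only *mtl-1* of these was (limma adjusted p = 0.0112). These 2 fits called 2202 and 97 genes in all. Of the 10 splits of the libraries, 4 and 2 gave as many calls, the real one included. The weights of the first fit converged in only 1 of them, the real split. The number of such calls therefore does not set the real groups apart.

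Over all 44 lists, camera with the preset correlation gave 17 higher and 3 lower, and none with an estimated correlation (adjusted p = 0.867 to 0.871 with an estimated correlation). That range held every list, also the major sperm proteins with all 31 members negative, so the lost calls do not tell one list from another. Without control replicate 3 it gave 15 higher and 3 lower, 16 of them called in both. Over the 10 splits of the 6 libraries into 3 against 3, camera with the preset correlation gave 14 to 27 lists, and the real split 20. The number of lists called therefore does not set JM03 against control apart from other groupings. The fry test, which asks whether a list's genes move on balance one way, gave no list, and its mixed form, which asks whether they change in either direction, gave the P450s (adjusted p = 0.00556). Without control replicate 3 the mixed form gave 3 lists, the P450s, UDP-glucuronosyltransferases and neuropeptides (adjusted p = 0.0236 for each). Neither form compares a list with other genes. For the neuropeptides, pharynx markers, proteasome subunits and mitochondrially encoded proteins the relative median was below 0 (-0.09, -0.03, -0.06 and -0.04) while camera pointed upward, without passing (camera adjusted p = 0.282 to 0.651).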

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

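The array weight, rescaling and combined quantile alternatives were chosen after the data were seen. Settings foreseen for read counts were not run, because the table holds TPM. The 17 calls (12 higher, 5 lower) were 15 with quantile normalization (14 of the 17 among them), 14 with no filter on 20614 genes, 13 at 5 TPM, where 4 of the 17 were not tested, and 17 with the 2-fold minimum or the non-robust prior. A pseudocount of 0.1 gave 13, 7 of them higher and 6 lower, of which 12 were among the 17. Leaving out single libraries gave 5 to 17 calls, 4 to 10 higher and 1 to 7 lower, and 9 to 19 lists higher and 3 to 4 lower; the fewest calls came without JM03 replicate 1, where 5 of the 17 remained. The filter at 5 TPM gave 9 lists higher. With an estimated correlation 0 lists were higher and 0 lower, so the calls of the P450s (relative median 0.30), UDP-glucuronosyltransferases (0.32), major sperm proteins (-1.97), sperm markers (-1.35) and ribosomal proteins (-0.62) all ended (adjusted p = 0.867 with an estimated correlation). With rescaled protein-coding genes 13 were called, 1 of them lower, because the non-coding genes had been removed.

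Same-numbered deviations correlated at -0.02, 0.08 and -0.15, and unlike-numbered ones at -0.278 to 0.291. Each deviation was taken from the mean of its group, so control replicate 3 enters those of all the controls. The check therefore cannot tell whether the replicate numbers pair the libraries. The replicate block gave 0 calls, 0 higher and 0 lower by limma, with 1600 genes at an unadjusted p below 0.05, and it ended the SKN-1 list call (relative median 0.06, camera adjusted p = 0.0717).

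Array quality weights gave control replicate 3 a weight of 0.03 and called 2202 genes, 855 higher and 1347 lower, while the gene-by-gene estimator gave it 0.028 and called 97, 66 higher and 31 lower. Both kept all 17 calls, so the number of added calls depends on the estimator. Among the genes the rule for names admits, both added *gst-5*, *mtl-1*, *col-3*, *ins-19*, *msp-74*, *ssp-9*, *clec-52* and *ugt-63*. The 2 fits moved the relative medians of the P450s to 0.571 and 0.473 and of the glutathione S-transferases to 0.551 and 0.505. Signs turned for *rpl-39* with quantile normalization (0.24), for the collagens with no filter (relative median -0.016), and without control replicate 3 for *daf-16* (-0.075), *gcs-1* (-0.121) and the histones (relative median 0.177). With array quality weights *daf-16*, *gcs-1* and *hsp-16.2* were at -0.079, -0.153 and 0.023 and the histones at 0.201, and with the gene-by-gene estimator *daf-16*, *gcs-1* and the histones were at -0.069, -0.130 and 0.186. Quantile normalization without control replicate 3 gave *daf-16* -0.102, *gcs-1* -0.136, *hsp-16.2* 0.009, the histones 0.199 and the neuropeptides 0.112. Over all single-library omissions *daf-16* ranged from -0.075 to 0.875, *gcs-1* from -0.121 to 1.025 and the histones from -0.554 to 0.177; the SKN-1 targets ranged from -0.040 to 0.326, the glutathione S-transferases from -0.111 to 0.460, the intestinal immune response genes from -0.042 to 0.445 and the nuclear hormone receptors from -0.010 to 0.104. The high end of both genes and the low end of the histones and of the first 3 of these lists came without control replicate 2. Control replicate 3 then makes up more of the control mean. It had the lowest control value of *daf-16* (20.28 TPM) and *gcs-1* (9.4 TPM) and the highest median deviation of the histones (0.547). For the 3 lists the cause was not tested. Read depth is unknown, so what it limits could not be computed.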

Other observations

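Gene families beyond the fixed lists were examined through 98 symbol classes. By Fisher's exact test only the *cyp* class passed, with 5 of 48 genes called higher (adjusted p = 8.7e-08). These are related genes and some are neighbours, so they may not be independent, as the test assumes. By camera with the preset correlation 15 classes were higher and 7 lower, 18 of these also without control replicate 3. The 16 tested *nspc* genes, a family of nematode-specific peptides, had a relative median of 0.91, with 15 positive (camera adjusted p = 0.00212; 1.43 without control replicate 3), and the 20 *vha* genes, subunits of the vacuolar proton pump, were all positive, with 0.69 (camera adjusted p = 0.00933; 0.24 without control replicate 3, with 19 positive). The 10 *irld* genes were all negative, with a relative median of -1.15 (camera adjusted p = 6.2e-07). No *nspc*, *vha* or *irld* gene was called, and an estimated correlation was not run for classes. Of the 12 genes called higher, 6 had another within 50 kb from start to start and 7 within that gap from end to start, a distance chosen after the positions were seen. By either measure 10000 random sets of 12 tested genes had at most 4 (permutation p = 1e-04, the smallest these permutations can give). The sets were drawn without regard to gene families, so this in part recounts the same *cyp* neighbours.

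All tests below were chosen after the results were seen, except the count of splits for the gene lists. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 17 genes and the highest other 2, so 1 split gave as many. For gene lists the real split gave 20 and the highest other 27, with 3 splits at 20 or more and none below 14. The number of lists called thus does not set the real split apart. With an estimated correlation the real split gave 0 lists. With array quality weights the real split gave 2202 and the highest other 5956, with 4 splits as large, but the weights converged in only 1 of the 10 fits, that of the real split. With the gene-by-gene estimator it gave 97 and the highest other 200, with 2 splits as large.

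The sperm lists had lower medians in JM03 and the oocyte markers and collagens higher ones, with no sperm, oocyte or collagen gene called over all genes in the main fit (*msp-74* passed without control replicate 3, limma adjusted p = 0.0428, and with a pseudocount of 0.1, limma adjusted p = 0.0416), all these list calls lost with an estimated correlation (adjusted p = 0.867 for each with an estimated correlation), and the collagen median at -0.016 with no filter. With array quality weights *msp-74*, *ssp-9*, *col-3* and the oocyte marker *perm-2* were among the 2202 genes called (limma adjusted p = 7.98e-04, 0.0163, 0.016 and 0.025). The first 3 were also called with the gene-by-gene estimator (limma adjusted p = 0.00189, 0.0451 and 0.0329). Control replicate 3 alone is argued against, since without it the major sperm protein median stayed at -1.42 relative to all genes, and so are short transcripts, since the lowest of 10000 lists of other genes matched on length and level had a median of -0.12, against -1.37. A candidate explanation, as a hypothesis, is that the libraries differ in the stage of the animals within as well as between groups: the difference of control replicate 2 from 1 and that of JM03 replicate 2 from 3, each the library higher in sperm genes minus the lower, correlated across the 12854 other genes (Pearson r = 0.32, genes not being independent). Both pairs were ordered by their sperm genes, and sperm-related genes outside the 2 lists may remain among the 12854. Part of this correlation may follow from that choice, so it cannot tell a difference in stage from one in sperm content. In both pairs the collagens (-1.09 and -0.78) and vitellogenins (-1.85 and -0.67) went against the sperm genes, but the intestinal immune response genes (-0.99 and 0.08), lysozymes (-0.49 and 0.31), P450s (-0.33 and 0.24) and epidermal antimicrobial peptides (-0.15 and 0.685) did so in the controls only, and 13 of the 44 lists took opposite signs in the 2 pairs. An effect of JM03 on the germ line stays open, as untested, and stage is not given in the sources used here.

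The same 2 explanations were set against the genes higher in JM03. A fit that did not use control replicate 3 called 9 of the 12 (highest limma adjusted p = 0.0386). The 12 were divided by that result, so the passing of the 9 is not evidence in itself. The log2 fold changes of the 12 ran from 1.72 to 6.26 in that fit and from 1.72 to 6.35 with the 6 libraries. Their size argues against control replicate 3 alone as the source of the changes. *cyp-35A5*, R05D8.9 and C37A5.5 did not pass in the fit without control replicate 3 (highest limma adjusted p = 0.108). The log2 fold changes of *cyp-35A5* and R05D8.9 were 2.39 and 1.91 there, against 2.41 and 1.94 with the 6 libraries. C37A5.5 was at 0 in control replicate 3 as in the other controls. The size of these 3 changes thus did not rest on that library, while their calls without it were lost. With each library's sperm gene level as a covariate in the other 5 libraries the median log2 fold change of the 12 genes was 3.55, against 3.46 without the covariate. The relative medians of the glutathione S-transferases, P450s and UDP-glucuronosyltransferases were -0.031, 0.28 and 0.11, against 0.46, 0.355 and 0.347. That covariate correlates at -0.858 with the group, the fit leaves 2 residual degrees of freedom, and the 12 genes had passed a test that favours close values within groups, so stage and treatment cannot be told apart by it. The difference between the groups was tested for these genes, but whether JM03 itself or a difference in stage gave it stays open. The 10 splits are too few for a share of chance under 0.05.

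Genes under 250 nt with at least 1 TPM in all controls and listed at 0 in all JM03 libraries numbered 8, against 0 the other way round. The 8 include F16A11.7 and F16A11.9, which are annotated at the same coordinates, so that locus is counted more than once. Few reads on short genes could give such values: among the 20 ordered splits 1, the real one, had as many, but the highest other had 7, which is within counting noise of 8, a bound that was set after this value was seen, where at first any excess over the other splits was to count against few reads. Depth and read length are not given in the sources used here, so loss of these RNAs in JM03 and few reads cannot be told apart.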
